A study of Mus musculus with 6 samples.

How the data were processed

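Total RNA was extracted with Trizol from Treg sorted by flow cytometry from mouse spleen and kept unstimulated, and sequencing libraries were made with the Lexogen QuantSeq kit, which reads tags at the 3′ end of polyadenylated transcripts, per the labels' protocols. The deposited files hold whole-number counts per gene symbol for each library, not normalized, with 23282 entries each, per the file headers and the values themselves. Bowtie2 and edgeR and the builds mm10 and hg19 are named, with no role or version, per the submitters' processing notes; what the human build served for, the counting program, the gene annotation, the strand setting and any filter are not given in the sources used here. Since counting was not stated to use strand, overlapping and antisense genes cannot be separated, and genes with near-identical copies are uncertain. A total of 35 symbols stood in 79 entries of each file, which were kept apart, and 14404 entries had a count in at least 1 library. No symbol with the mitochondrial prefix mt- was present, so no mitochondrial share could be given.

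Each library was assigned to wild type or IPMK cKO by its genotype label, with 3 libraries per group. All libraries were used. The groups, the tests, the 26 gene lists, the rule for the genes named and most of the alternative settings were chosen before the data were examined. The replicate numbers, which both groups share, were not in the model, because nothing in the labels ties a number to an animal, litter or day.

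Genes were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes were kept by filterByExpr with its default minimum of 10 counts, which left 10475, and IPMK cKO was compared with wild type by the quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are counts scaled to a common library size (CPM) on the TMM-scaled library sizes, with the SD over the 3 libraries of a group, and log2 fold changes are IPMK cKO over wild type with the SE from the same model. The SE was taken as the estimate over the square root of the F statistic. Gene lists with at least 5 tested members, 24 of the 26, were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated for each list, where it also takes its p from the residual degrees of freedom of the libraries. Fry from limma was run as a self-contained test. Members of a list were also adjusted over the list alone. Single values per library were compared by exact permutation tests, two-sided, whose smallest p with 3 against 3 libraries is 0.1. Where a group had no count of a gene, a fold was computed against a floor of 3 counts over the group; floors cover counting error only, since reads without molecular identifiers are not independent molecules.

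Named genes followed a fixed rule. They were Ipmk; the called genes with the largest changes or, as here where fewer than 5 were called in each direction, the 5 with the smallest p in each direction, given as not called and passing over predicted genes and receptor or immunoglobulin segments; up to 4 tested members of each list with the smallest p, and up to 6 for the effector, central, core, calcium and T cell receptor lists; 21 genes of Treg biology fixed by name; and the 4 most abundant members of each list of another cell type. Gzmb, Il10, Cxcr6, Phospho1, Gdpd3 and Tmsb4x, and S100a4 in the closing part, were named after their values were seen. Some genes that the rule takes are not reported here or drawn in the figures. Of the genes tested, 96.1% had their symbol in GENCODE M21, from which coordinates on mm10 were taken.

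The depth was 7464546 to 8980395 counts per library, of which 5287300 to 7130660 lay outside Rn45s. The procedure was tested on simulated counts for the 10475 genes with the means, library sizes and dispersions of this comparison and 200 changed genes in each of 3 runs per fold. The changed genes were drawn from those with a mean of at least 5 CPM. With these dispersions 0%, 24.0% and 51.8% of genes changed 2-, 4- and 8-fold were recovered, and with the dispersions scaled to 0.1 these shares were 63.3%, 92.0% and 98.0%. Camera called the effector list in 5 of 5 simulations with a 2-fold shift and in 0 of 5 with none. Simulated genes varied independently of each other, whereas the estimated correlation within the real effector list was 0.0518. These runs therefore do not show how often camera calls a list whose members vary together. The alternatives were DESeq2 1.42.0, limma-voom, robust quasi-likelihood, other size factors, other filters on low counts, the replicate number as a block, leaving out each library in turn, other thresholds, and removal of ribosomal protein and haemoglobin genes. Added after the data were seen were removal of Rn45s, voom with sample quality weights, and removal of both libraries that lay apart on the principal components.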

Results

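Regulatory T cells (Treg), the CD4 T cells that restrain immune responses, were sorted by flow cytometry from the spleens of C57BL/6 mice and their RNA was sequenced without stimulation. The comparison asked how the transcriptome of Treg that lack inositol polyphosphate multikinase (IPMK) differs from that of wild type Treg. IPMK is a kinase that adds phosphates to inositol phosphates and phosphoinositides, and the study concerned effector Treg and calcium influx. There were 3 wild type and 3 IPMK conditional knockout (IPMK cKO) libraries, each described as a biological replicate. The labels do not say whether these came from separate animals, so p-values measure only the spread between these samples, which may be partly technical. Total counts were 7464546, 7743187 and 8246993 in the wild type libraries and 8980395, 8363324 and 8897212 in the IPMK cKO libraries. Every IPMK cKO library was the deeper (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow). The adjusted p of that exact test was 0.5 over the library measures compared. Counts outside the ribosomal RNA precursor Rn45s overlapped between the groups. They were 5896638, 5287300 and 6865772 in wild type and 6172832, 5676469 and 7130660 in IPMK cKO replicates 1 to 3.

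The 45S ribosomal RNA precursor Rn45s took 23.2% ± 7.71 of the counts in wild type and 27.7% ± 6.85 in IPMK cKO libraries (SD, n = 3 each, exact permutation p = 0.6). Between 10311 and 12526 genes had at least 1 count in a library. The libraries did not group by genotype. IPMK cKO replicate 1 lay apart on the first principal component (38.7% of the variance) and wild type replicate 1 on the second (24.2%). Pearson correlations of log2 CPM across genes were 0.754 to 0.845 within wild type, 0.667 to 0.773 within IPMK cKO and 0.659 to 0.866 between the groups. In IPMK cKO replicate 1, 16 of the 500 most abundant genes were more than 4-fold from the median of the other libraries, against 0 in each other library.

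Ipmk (ENSMUSG00000060733, chromosome 10, 71347763 to 71433327 on the plus strand of mm10) had 129, 77 and 99 counts in the wild type libraries and 3, 21 and 0 in IPMK cKO replicates 1 to 3. Its mean level was 12.1 ± 2.95 CPM in wild type and 1.06 ± 1.48 CPM in IPMK cKO (SD, n = 3 each), an 11.5-fold ratio of means. Every IPMK cKO library lay below every wild type library. A count of 0 in IPMK cKO replicate 3 allows up to 0.304 CPM there (3 counts, counting error only). The estimated log2 fold change was −3.51 (SE 1.75) with an edgeR adjusted p of 0.9999, and the exact permutation test gave its smallest possible p of 0.1. Tags from the 3′ end of a transcript report a deletion only if they lie in the deleted part or if the deletion lowers the transcript. The deleted part of Ipmk is not given in the sources used here, so the count describes transcript abundance.

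**Figure D1:**
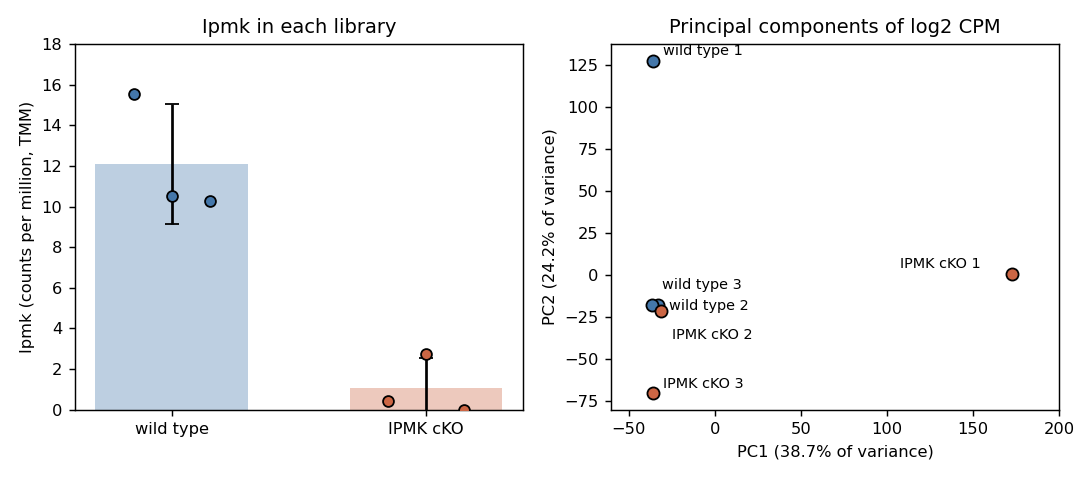
Left, Ipmk in TMM-scaled CPM in each library, with bars at the group mean and error bars of 1 SD (n = 3 each). The IPMK cKO libraries lie at 0.422, 2.74 and 0 CPM, all below the wild type libraries at 15.5, 10.5 and 10.3 CPM. Right, the first and second principal components of log2 CPM, which carry 38.7% and 24.2% of the variance, with 1 point per library; IPMK cKO 1 and wild type 1 lie apart.

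Among single genes, S100a6 and S100a11, calcium-binding proteins of the S100 family, had the smallest p-values of the genes lower in IPMK cKO. The chromatin organizer Satb1 and the RNA helicase Ddx1 were among the 5 with the smallest p-values of those higher. None of the 10475 genes tested was called in either direction by edgeR's quasi-likelihood test at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 143 higher and 125 lower genes, where 524 would be expected with no effect. DESeq2 called 1 higher gene, Phospho1 (0, 0.14 and 0 CPM in wild type and 21.8, 3.27 and 6.39 CPM in IPMK cKO). It called 3 lower genes, S100a6, S100a11 and Smpdl3b. The 3 libraries of a group lay wholly above or below those of the other for 10.4% of the genes (496 higher and 593 lower), where chance gives 10%. The biological coefficient of variation was 0.809. Over 5 equal bins of genes by abundance its median went from 1.49 in the lowest to 0.330 in the highest. In simulated counts with the spread of these libraries, 0% of genes changed 2-fold, 24.0% of those changed 4-fold and 51.8% of those changed 8-fold were recovered over 10475 genes. The changed genes had a mean of at least 5 CPM, so these shares do not cover the least abundant genes. Differences of 2-fold in single genes were not detectable here.

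The other genes with the smallest p-values were not called by edgeR, and 1 of them, Smpdl3b, was called by DESeq2 as given above. Higher in all 3 IPMK cKO libraries were Ddx1 (log2 fold change +1.56, SE 0.40) and Galnt10, an enzyme of mucin-type glycosylation (+1.84, SE 0.50). So were the calcium/calmodulin-dependent kinase kinase Camkk2 (+1.93, SE 0.53) and the death-domain receptor Tnfrsf25 (+1.39, SE 0.40). Lower in all 3 were the non-coding transcript AW112010 (−1.31, SE 0.34; 260 ± 57.0 against 105 ± 34.4 CPM) and the decoy interleukin receptor Il1r2 (−2.87, SE 0.76; 49.0 ± 40.2 against 6.70 ± 1.39 CPM). Smpdl3b, a membrane phosphodiesterase, had no count in the IPMK cKO libraries. Against a floor of 3 counts over the group it was 74.4-fold lower, which covers counting error only and not the spread between libraries.

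Genes of effector Treg, the activated Treg that home to tissues, fell together in IPMK cKO by the list test (camera adjusted p = 1.12e-08 over the 24 lists tested). The call was lost with an estimated correlation (adjusted p = 0.314, unadjusted p = 0.0131) and in fry (adjusted p = 0.0614). By edgeR 0 of the members passed singly over all genes, while DESeq2 called S100a6 and S100a11. Of the 39 tested members of the list, 32 had estimates below 0 and 7 above, with a median log2 fold change of −0.74. In all, 18 members were lower in every IPMK cKO library than in any wild type library against 0 higher. S100a6 was 230 ± 41.0 CPM in wild type and 73.3 ± 11.6 CPM in IPMK cKO (log2 fold change −1.65, SE 0.30). S100a11 was 283 ± 52.2 and 89.3 ± 22.5 CPM (−1.67, SE 0.31; SD, n = 3 each). The list's share of the counts outside Rn45s was 0.732% ± 0.0301 in wild type and 0.432% ± 0.0471 in IPMK cKO (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The shares in IPMK cKO replicates 1 to 3 were 0.396%, 0.485% and 0.415%.

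By edgeR over all genes tested, 0 members of this list rose, 0 fell and 39 did not pass. DESeq2 called S100a6 and S100a11 lower over all genes (DESeq2 adjusted p = 0.000737 and 0.000971). Adjusted over the list alone, 2 fell, S100a6 and S100a11 (edgeR adjusted p = 0.00483 for each). Both passed in this way in 16 of 16 alternative settings of the edgeR fit. The inhibitory receptor Klrg1 (−1.35, SE 0.43), the transcription factor Maf (−0.96, SE 0.31) and the glutaredoxin Glrx (−1.70, SE 0.56) followed with edgeR adjusted p = 0.0875 over the list alone. The transcription factors Prdm1, Batf and Irf4 had log2 fold changes of −0.87 (SE 0.47), −0.74 (SE 0.38) and −0.70 (SE 0.67). The costimulatory receptor Icos had −0.67 (SE 0.29), the adhesion receptor Cd44 −0.69 (SE 0.55) and S100a10 −0.91 (SE 0.33). Gzmb, which encodes the protease granzyme B, had 25, 16 and 29 counts in wild type and none in IPMK cKO. Against a floor of 3 counts over the group it was 22.8-fold lower, which covers counting error only and not the spread between libraries. It was not called (edgeR adjusted p = 0.9999 over all genes). Placing it at that fold left the list's median at −0.74. Of the members too low to test, Il10 had 0, 56 and 154 counts in wild type and 0 in each IPMK cKO library, and Tigit had 0, 37 and 0 against 1, 0 and 0.

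The count of effector list members that passed adjusted over the list alone was 4 without IPMK cKO replicate 1, 4 without that library and wild type replicate 1, 9 without IPMK cKO replicate 2 and 9 with no filter on low counts.

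**Figure D2:**
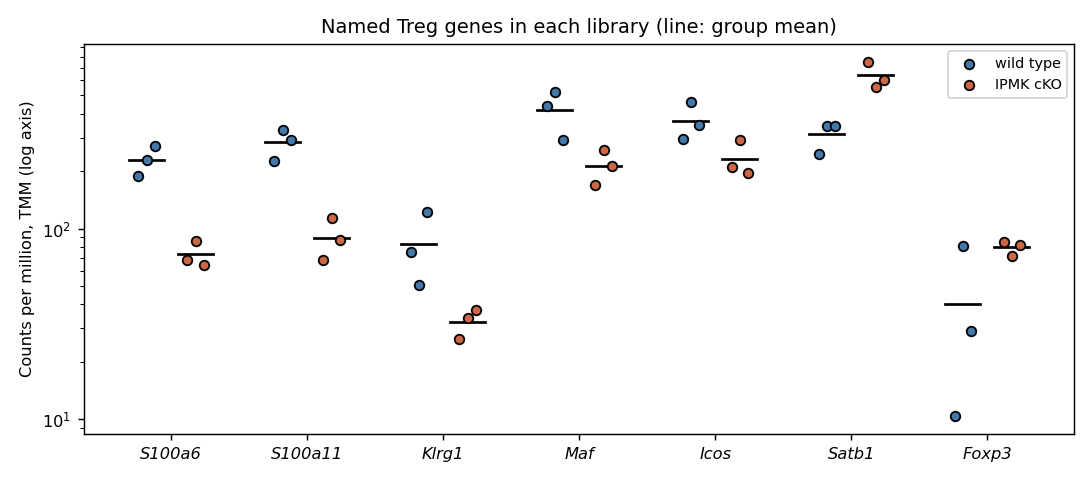
TMM-scaled CPM (log axis) of 7 named Treg genes in each library, with 1 point per library and a line at each group mean. S100a6, S100a11, Klrg1, Maf and Icos lie lower in all 3 IPMK cKO libraries, Satb1 higher, and Foxp3 overlaps, with wild type at 10.4, 80.6 and 29.0 CPM.

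Genes of central or resting Treg, which recirculate through lymphoid organs, rose together by the list test (camera adjusted p = 0.0198). The call was lost with an estimated correlation (adjusted p = 0.766) and in fry (adjusted p = 0.756), and 0 of the members passed singly. Of 28 tested members, 21 had estimates above 0 and 7 below (median log2 fold change +0.39), with 9 higher and 1 lower in every IPMK cKO library. The list's mean log2 level relative to wild type was −0.33, 0.06 and 0.27 in wild type replicates 1 to 3. It was −0.11, 0.37 and 0.54 in IPMK cKO, so the groups overlapped (exact permutation p = 0.4). Its share of the counts outside Rn45s was 0.625% ± 0.0492 in wild type and 0.802% ± 0.0891 in IPMK cKO (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Satb1 was 314 ± 57.2 CPM in wild type and 637 ± 102 CPM in IPMK cKO (SD, n = 3 each; +1.02, SE 0.27). The log2 fold changes were +0.75 (SE 0.29) for the receptor Il6ra, +0.80 (SE 0.31) for Klf3, +0.67 (SE 0.28) for the transcription factor Lef1 and +0.87 (SE 0.41) for the sodium pump subunit Atp1b1. They were +0.43 (SE 0.38) for Tcf7, +0.36 (SE 0.25) for the survival factor Bcl2 and −0.06 (SE 0.37) for the chemokine receptor Ccr7. Over all genes 0 members rose, 0 fell and 28 did not pass, and adjusted over the list alone 0 rose or fell. The call by limma's camera was also lost without wild type replicate 2 (median +0.34, adjusted p = 0.243), without IPMK cKO replicate 2 (+0.33, 0.120) and without IPMK cKO replicate 3 (+0.24, 0.326).

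**Figure D3:**
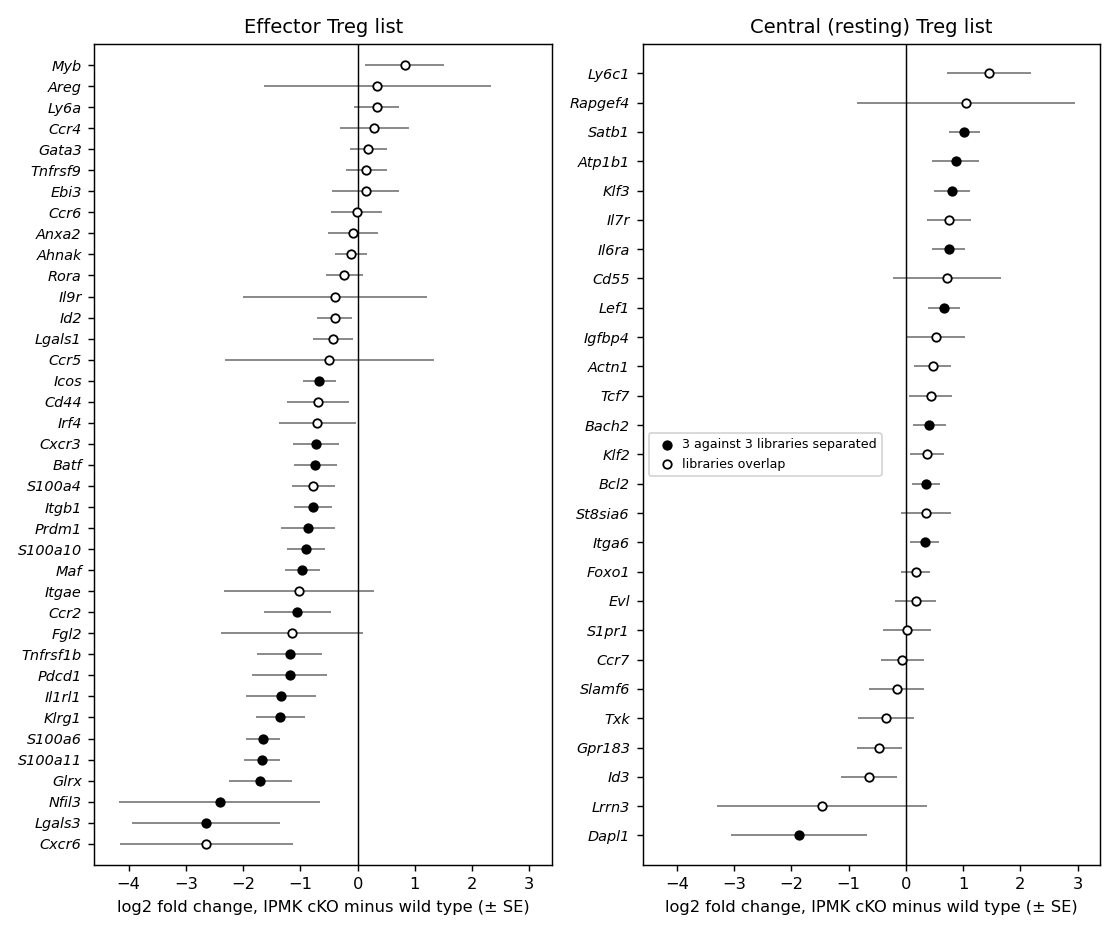
Log2 fold change of IPMK cKO over wild type with 1 SE for the tested members of the effector Treg list (left) and the central or resting Treg list (right), leaving out Gzmb, which had no count in IPMK cKO, and 1 further member on the right. Filled points are genes whose groups do not overlap, and open points are genes whose groups overlap; the list medians are −0.74 and +0.39.

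The genes that define Treg as a lineage did not pass as a group. Of 24 tested members, 9 had estimates above 0 and 15 below (median −0.13, camera adjusted p = 0.682), and 0 passed over all genes or adjusted over the list alone. Foxp3, the transcription factor of the Treg lineage, was 40.0 ± 36.4 CPM in wild type and 79.8 ± 6.92 CPM in IPMK cKO (SD, n = 3 each; +0.998, SE 0.61). The high-affinity interleukin-2 receptor chain Il2ra (+0.11, SE 0.29), the checkpoint receptor Ctla4 (−0.18, SE 0.33) and the transcription factor Ikzf2 (−0.45, SE 0.32) had estimates within 2 SEs of 0. The smallest p-values were those of Socs2, a suppressor of cytokine signalling (−0.95, SE 0.36), Tnfrsf18 (+0.63, SE 0.29) and Gpr83 (+0.90, SE 0.43). Next were the ectonucleotidase Nt5e (−1.03, SE 0.51), Nrp1 (−0.56, SE 0.28) and Ecm1 (+0.65, SE 0.36). Gpr83 rose adjusted over the list alone only without IPMK cKO replicate 1 (edgeR adjusted p = 0.0120).

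For the calcium question, 38 tested genes of calcium entry and handling had a median log2 fold change of +0.10, with 23 estimates above 0 and 15 below (camera adjusted p = 0.569). The calcineurin subunit Ppp3cb was 49.7 ± 8.46 CPM in wild type and 88.0 ± 22.2 CPM in IPMK cKO (SD, n = 3 each; +0.82, SE 0.36). The endoplasmic reticulum calcium release channels Itpr2 and Itpr3 had estimates of +0.41 (SE 0.25) and +0.99 (SE 0.60). Orai1, the pore of the store-operated channel, had +0.67 (SE 0.43), its activator Stim1 +0.38 (SE 0.49) and Itpr1 −0.15 (SE 0.57). The calcium pumps Atp2a3 and Atp2b4 had +0.85 (SE 0.45) and −0.71 (SE 0.41). Of the 31 tested inositol phosphate and phosphoinositide enzymes, 12 had estimates above 0 and 19 below (median −0.21, camera adjusted p = 0.412). Ipmk itself, the targeted gene, was a member of this list and counted among those below 0. The median was +0.03 without IPMK cKO replicate 1, with 16 above 0 and 15 below, and −0.44 without replicate 2. Among them were the PI3K regulatory subunit Pik3r1 (+0.70, SE 0.29), the inositol monophosphatase Impa1 (−0.83, SE 0.46), Ppip5k1 (+2.21, SE 1.09) and Itpkb (+0.12, SE 1.43). In both lists 0 members passed over all genes or adjusted over the list alone.

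Genes induced by the T cell receptor (28 tested) had a median of −0.11 and a camera adjusted p of 0.343. Nfkbid was at +1.09 (SE 0.50), Egr2 at −1.23 (SE 0.69), Relb at −0.95 (SE 0.53) and Rgs16 at −1.69 (SE 1.09). Nr4a1, an early gene of receptor signalling, was at −0.68 (SE 0.89), Spry1 at −1.86 (SE 1.46) and Ifrd1 at +0.60 (SE 0.48). Their mean log2 level relative to wild type was −1.63 in IPMK cKO replicate 1, −0.14 in replicate 2 and 0.21 in replicate 3. Without IPMK cKO replicate 3 the list was called lower by limma's camera (adjusted p = 0.0419). The 18 FOXO1 target genes had a median of +0.36 (camera adjusted p = 0.230). Il7r was at +0.75 (SE 0.38), Trib2 at +0.52 (SE 0.29) and the pro-apoptotic gene Bcl2l11 at +0.51 (SE 0.31). The 18 tested targets of interleukin-2 and STAT5 had a median of +0.13 (camera adjusted p = 0.732). Their smallest p-values were those of Socs2 (−0.95, SE 0.36), Prdm1 (−0.87, SE 0.47) and the cyclin Ccnd2 (+0.45, SE 0.25). The 11 TGF-beta response genes had a median of −0.07 (camera adjusted p = 0.569). Tgfbr1 was at +0.61 (SE 0.40), Smad3 at −0.50 (SE 0.40), Skil at −0.35 (SE 0.34) and Tgif1 at −0.65 (SE 0.83). None of the members of these lists passed over all genes or adjusted over the list alone.

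Cell cycle genes fell together by the list test, with 31 of 38 estimates below 0 and a median log2 fold change of −0.48 (camera adjusted p = 0.0198, adjusted p = 0.838 with an estimated correlation). The proliferation marker Mki67 was 45.3 ± 19.3 CPM in wild type and 20.3 ± 4.76 CPM in IPMK cKO (SD, n = 3 each; −1.16, SE 0.53), and the cyclin Ccne2 had −1.22 (SE 0.70). The replication factor Cdc45 had no count in IPMK cKO. Against a floor of 3 counts over the group it was 53.3-fold lower, which covers counting error only. The mean log2 level of the list relative to wild type was −1.17, 0.35 and 0.82 in wild type replicates 1 to 3 and −1.56, −0.83 and −0.04 in IPMK cKO. Both libraries numbered 1 were the lowest of their group. The call was lost without wild type replicate 3 (median −0.24, adjusted p = 0.383), without IPMK cKO replicate 1 (−0.55, 0.0723) and without IPMK cKO replicate 2 (−0.60, 0.266). The median was −1.09 without IPMK cKO replicate 3. Ribosomal protein genes rose together by the list test, with 34 of 44 estimates above 0 and a median of +0.28 (camera adjusted p = 0.0301, adjusted p = 0.838 with an estimated correlation). Their share of the counts outside Rn45s was 7.17% in IPMK cKO replicate 1, 4.53% in replicate 2 and 6.15% in replicate 3, against 5.85%, 4.50% and 5.53% in wild type. Rps20 was 7402 CPM in IPMK cKO replicate 1 and 1832 to 2387 CPM in the other libraries (+1.04, SE 0.44). Rpl35 (+0.88, SE 0.44), Rpl8 (+0.79, SE 0.43) and Rps27 (+0.68, SE 0.40) were likewise highest there. These values are uncertain where reads are shared with processed pseudogenes. The call was lost without IPMK cKO replicate 1 (median +0.05, adjusted p = 0.779) and without wild type replicate 2 (+0.14, 0.638). It was also lost without IPMK cKO replicate 3 (+0.23, 0.309) and without both libraries numbered 1 (+0.13, 0.109). In the cell cycle and ribosomal protein lists 0 members passed over all genes or adjusted over the list alone.

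The next 5 lists were not called, and 0 of their members passed over all genes or adjusted over the list alone with all libraries. Chemokine receptors and migration genes (23 tested) had a median of −0.28 (camera adjusted p = 0.230). The gut-homing receptor Ccr9 was at 31.2 ± 11.1 CPM in wild type and 74.5 ± 5.96 CPM in IPMK cKO (SD, n = 3 each; +1.25, SE 0.41). The inflammatory receptor Ccr2 was at −1.05 (SE 0.58) and the integrin chain Itgb1 at −0.78 (SE 0.33). Without IPMK cKO replicate 2, Itgb1 and Cxcr6 fell adjusted over the list alone (edgeR adjusted p = 0.0262 and 0.0115). Interferon-stimulated genes (39 tested) had a median of +0.12 (camera adjusted p = 0.324). Slfn1 was at +0.91 (SE 0.28), the transcription factor Irf7 at +1.70 (SE 0.57), Ly6e at +0.60 (SE 0.40) and Isg20 at +0.47 (SE 0.38). Apoptosis regulators (22 tested) had a median of −0.50 (camera adjusted p = 0.324), with Bid at −1.55 (SE 0.88). The near-identical paralogs Bcl2a1d and Bcl2a1b, whose reads may be split uncertainly, were at −1.31 (SE 0.71) and −1.13 (SE 0.67). Effector T cell cytokines and regulators (9 tested) had a median of −0.54 (camera adjusted p = 0.541). The transcription factor Eomes was at +3.08 (SE 1.47), Il18r1 at −0.72 (SE 0.38), Cd40lg at −0.78 (SE 1.06) and Il21 at −2.77 (SE 2.45). Immediate early and heat shock genes (21 tested) had a median of +0.01 (camera adjusted p = 0.992). The AP-1 gene Junb was at −0.93 (SE 0.36), Jund at +0.70 (SE 0.45), Dnajb1 at −0.65 (SE 0.38) and Klf4 at +1.80 (SE 1.86).

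Metabolic lists had medians between −0.03 and +0.08, and 0 members passed over all genes or adjusted over the list alone. Glycolysis and hypoxia genes (23 tested) had a median of +0.05 (camera adjusted p = 0.814), with hexokinase Hk1 at +0.82 (SE 0.41) and Ldha at +0.53 (SE 0.34). Growth genes of mTORC1 and MYC (25 tested) had a median of −0.03 (camera adjusted p = 0.814), with Ddx21 at +0.52 (SE 0.27), Mthfd2 at +0.67 (SE 0.35) and Atf4 at +1.05 (SE 0.56). Atf4 was 757 CPM in IPMK cKO replicate 1 and 145 to 204 CPM elsewhere. Cholesterol synthesis genes (21 tested) had a median of +0.04 (camera adjusted p = 0.843). Dhcr7 was at +1.75 (SE 0.88), Idi1 at −3.04 (SE 1.62) and their regulator Srebf2 at −0.95 (SE 0.43). Oxidative phosphorylation genes (32 tested) had a median of +0.08 (camera adjusted p = 0.959), with Ndufa7 at −0.65 (SE 0.34) and Ndufa2 at +0.63 (SE 0.41).

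Markers of other cells that a spleen sort could hold were low in every library. The 87 markers of B, myeloid, CD8 T, NK and erythroid cells and platelets together took 0.0717% to 0.101% of the counts outside Rn45s. The immunoglobulin genes Ighm, Ighd and Igkc of the B and plasma cell list had no entry in the counts, so this share leaves them out. B and plasma cell genes (9 tested, median +0.57, camera adjusted p = 0.512) were led by Cd74 at 5.53 to 48.5 CPM in wild type and 12.8 to 58.5 CPM in IPMK cKO. The median was −0.38 without IPMK cKO replicate 1 and −0.65 with no filter on low counts. Cr2 was at 3.68 ± 1.48 and 13.6 ± 12.9 CPM. Myeloid genes (7 tested, median −0.15, camera adjusted p = 0.814) were led by the protease gene Ctss, which T cells also express, at 276 ± 62.2 and 272 ± 14.4 CPM, with Cst3 at 58.9 ± 10.9 and 38.3 ± 29.6 CPM. CD8 T and NK cell genes (6 tested, median −0.18, camera adjusted p = 0.975) were led by Ctsw at 62.1 ± 14.5 and 115 ± 82.3 CPM and Ccl5 at 47.7 ± 14.3 and 21.3 ± 16.7 CPM (SD, n = 3 each). Their member Eomes was higher in every IPMK cKO library, at 1.92 ± 1.92 and 16.4 ± 5.51 CPM. Ctsw rose adjusted over the list alone only without IPMK cKO replicate 2 (edgeR adjusted p = 0.0468). Of the erythroid and platelet genes 4 could be tested, too few for a list test. Hba-a1, whose reads can be shared with its paralog, was 16.3 ± 25.4 and 3.67 ± 3.72 CPM. The list of conventional naive CD4 T cell genes (15 tested, median +0.21, camera adjusted p = 0.597) held Cd4 itself at 417 ± 37.7 and 349 ± 87.7 CPM. In it 1 member, Satb1, rose adjusted over the list alone (edgeR adjusted p = 0.0499), a call kept in 7 of 16 alternative settings. Lef1, Themis (+1.04, SE 0.50) and Dapl1 (−1.87, SE 1.19) were its next members by p-value. In the B, myeloid, CD8 T and NK cell lists 0 members passed over all genes or, with all libraries, adjusted over the list alone. Xist had 5165 to 7076 counts and the Y-linked genes 0 to 3 counts in every library, so the groups did not differ in sex. Tsix, which overlaps Xist on the other strand, cannot be told apart from it without strand.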

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

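The settings chosen only after the data were seen were the sample quality weights, leaving out Rn45s, and leaving out wild type replicate 1 and IPMK cKO replicate 1 together. The count of called genes, 0 higher and 0 lower by edgeR, was 1 higher and 3 lower with DESeq2, 1 lower with voom and quality weights, 1 lower without both libraries numbered 1, and 0 to 1 lower on leaving out each library; the cause was not tested. The effector list lost its camera call with an estimated correlation (adjusted p = 0.314) and in fry (0.0614) only, with 4.93e-10 to 6.00e-05 on leaving out each library. For the central, cell cycle and ribosomal protein lists the estimated correlation gave 0.766, 0.838 and 0.838 and fry 0.756, 0.756 and 0.764. The estimated correlations of 0.0390, 0.175 and 0.415, and 0.0518 for the effector list, lie above the preset 0.01, which raises camera's p. That does not account for the lost calls alone. With an estimated correlation, camera also takes its p from the few residual degrees of freedom of the libraries, which raises p further. Camera's unadjusted p also rose for the FOXO1 targets, from 0.0576 to 0.119, where the estimate of 0.00441 lay below the preset value. On leaving out each library, camera from limma gave adjusted p from 0.00157 to 0.326 for the central list, 8.39e-07 to 0.383 for the cell cycle and 0.000462 to 0.779 for the ribosomal proteins, with 0.109 for the last without both libraries numbered 1, and 0.0419 to 0.840 for the T cell receptor list; the cause was not tested. Of 332 list results under alternatives, 313 stayed on the same side of the threshold, 18 lost and 1 gained a call, 0 reversed with a call and 36 changed direction without one. On leaving out a single library, the median changed sign for the inositol, calcium, TGF-beta, glycolysis, growth, cholesterol, oxidative phosphorylation, and immediate early and heat shock lists, and for the B cell, myeloid, CD8 T and NK cell, and conventional T cell lists. Of 1971 alternative log2 fold changes of 133 named genes, 1939 kept their sign and 32, in 18 genes, did not, and 3 were called, all by DESeq2. Scaling by total counts only moved the median of all genes from 0.03 to −0.17; relative to it the effector list (median −0.95) stayed lower and the central list (0.20) higher.

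Whether the shared replicate numbers pair the libraries is not settled. Same-numbered libraries deviated together with correlations of 0.0454, 0.0877 and 0.0265, none above 0.1 but all positive. Libraries of different numbers had −0.0609 to −0.00106. Deviations within a group sum to 0, so positive values for the same number force negative ones elsewhere, which add no evidence. Each library correlated best with its own number, a weak hint from the data and not the design. With so few libraries such a match also arises easily by chance. Wild type replicate 2 and IPMK cKO replicate 2 also had the highest correlation of log2 CPM of any pair of libraries (0.866). These libraries had the highest mean correlations with all others too (0.804 and 0.784), so that value says little on pairing. With the replicate block 0 genes were called higher and 0 lower, the effector list had a camera adjusted p of 4.93e-07, and the 4 list calls stood, while Satb1 lost its call over its list alone. Dispersions scaled to 0.1 brought the recovery of simulated 2-fold changes from 0% to 63.3%. Less spread must raise recovery in such a simulation, so this does not show what limits single genes in the real libraries. The biological coefficient of variation was 0.691 without both libraries numbered 1 and 0.566 among the 7844 genes with a mean of at least 10 CPM. It was lower in the more abundant genes, so a limit from depth is not excluded, and depth was not varied.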

Other observations

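The tests chosen only after the result was seen were those on IPMK cKO replicate 1 (its removal, its most abundant genes, GC content and length, and genotype), the one on conventional T cells, and the splits for the central, cell cycle and ribosomal protein lists.

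Gdpd3, which encodes a phosphodiesterase that cleaves lysophospholipids, was 241, 279 and 326 CPM in the wild type libraries and 320, 5.62 and 7.71 CPM in IPMK cKO replicates 1 to 3, with a log2 fold change of −1.34 (SE 1.12) and no call. It was called lower without IPMK cKO replicate 1 (−5.40, edgeR adjusted p = 7.66e-05), without both libraries numbered 1 (−5.49, edgeR adjusted p = 0.00179) and by limma-voom with sample quality weights (−4.90, adjusted p = 0.0359), against 0.9999 over all libraries. It lies on chromosome 7 (126766334 to 126775649), apart from Ipmk on chromosome 10. S100a4, a neighbour of S100a6 on chromosome 3, was 427 CPM in IPMK cKO replicate 1 and 206 and 150 CPM in replicates 2 and 3, against 394 to 522 CPM in wild type. Of the genes tested, 17 had no count in any IPMK cKO library and 1 had none in any wild type library, a difference that was not tested.

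The absence of called genes was weighed against the quality of the libraries. Removal of IPMK cKO replicate 1, the library farthest from the others, left 1 called gene. The count of called genes cannot decide here, since fewer libraries also give less power. The biological coefficient of variation was 0.787 without that library, over 11138 genes, against 0.809 with all libraries, over 10475 genes. Much of the spread thus remained without it. Leaving out any other single library gave 0.854 to 0.927. A loss of transcripts in library making could add spread: genes with a median of at least 20 CPM in the other libraries were at 0 in 0.286% of cases (median over libraries), from 0.0151% in IPMK cKO replicate 2 to 1.06% in replicate 1, where counting error alone gives almost none. That value lies between the bounds set for and against low complexity, so the explanation stays open. In 10 of the 10 splits of the 6 libraries 0 genes were called, the real split included (highest other 0), and 10 splits are too few to judge chance.

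The fall of the effector Treg list was not carried by IPMK cKO replicate 1, since its median was −0.70 without that library. Drop-out of low genes is argued against by 0% of 10000 random lists of matched expression having a median as low, the lowest being −0.35. These draws treat genes as independent, so the share does not measure the spread between libraries. IPMK cKO replicate 2, with the fewest such genes at 0 (0.0151%), had the smallest fall of its group. Wild type replicate 1, at 0.632%, had a mean log2 level of −0.03 for the list. More conventional T cells in the knockout sorts were taken to lower Treg core genes at least as much, a premise not tested here. The core median lay 0.61 above the effector median on the log2 scale (permutation test of genes between the 2 lists, p = 0.00916). That test treats genes as independent, so its p does not measure the spread between libraries. Mean log2 levels relative to wild type in IPMK cKO replicates 1 to 3 were −0.59, 0.15 and −0.40 for the core list. For the effector list they were −1.46, −0.63 and −1.34. If the premise holds, these values argue against such cells as the whole cause. Foxp3 was at +0.998 (SE 0.61), with overlapping groups. Of 15 conventional naive CD4 T cell genes, 4 were higher and 1 lower in every IPMK cKO library (median +0.21, camera adjusted p = 0.597; median −0.15 without IPMK cKO replicate 2), so a smaller excess of such cells stays open. The list's −log10 p was 9.33 in the real split and at most 2.35 in the others (1 of 10 splits as large), and 10 splits are too few for a share under 0.05. A change in the share of effector cells among Treg and a change of expression in each cell were not tested and stay open.

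IPMK cKO replicate 1 stood apart in highly expressed genes, with Tmsb4x, an actin-binding peptide gene, at 792 CPM outside Rn45s there and 8120 to 10414 elsewhere. Random loss of molecules would leave abundant genes in place, yet 16 of the 500 most abundant lay over 4-fold away. After GC content and length were taken out, the variance of its deviation was 2.82 times the highest of the other libraries. Of its 171 genes with a mean of at least 50 CPM and over 4-fold from wild type, 0.585% (1) were over 2-fold the same way in both other IPMK cKO libraries, which restates that it stood apart and decides nothing on genotype. Markers of other cells took 0.0864% of its counts outside Rn45s, within the range of the other libraries, and a difference in the animal or in library preparation stays open and untested.

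For the other called lists, the camera −log10 p in the real split and the highest in the other splits of the 6 libraries were 2.61 and 2.28 for the central list (1 of 10 splits as large), 2.67 and 8.79 for the cell cycle list (2 of 10) and 2.30 and 8.35 for the ribosomal protein list (4 of 10). The 10 splits are too few for a share under 0.05. The splits with the highest values for the cell cycle and ribosomal protein lists both placed wild type replicate 1 and IPMK cKO replicate 1 together.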
